A study of Homo sapiens with 4 samples.

How the data were processed

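Ribosome profiling libraries were made from HEK293T cells treated with benzamide or cycloheximide, 2 libraries each, at 350 µM for 1 min. Per the labels' protocols, lysates were digested with nuclease, ribosomes were pelleted through sucrose, and short footprints were size-selected on a gel. The linker ligated to the footprints carried 1 barcode for each treatment, ligations were pooled, and ribosomal RNA was then depleted. Linker barcode and treatment therefore cannot be told apart. The submitters' processing notes name cutadapt 1.8.1, Bowtie2 2.3.2, STAR 2.7.0e, SAMtools 1.5, UMI-tools 1.0.0, and the builds GRCh38 and hg38. The role and order of these tools, the counting rule, its use of strand and the annotation are not given in the sources used here. If reads shared between near-identical genes were split or dropped, the values of such genes are uncertain. If molecular identifiers were not used to remove duplicates, counts are not independent molecules, and every counting interval here covers counting error only.

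The only file is 1 table of the comparison, with the column names of DESeq2 results, per the file headers. The deposited mean per gene is a signal, the mean over the 4 libraries of counts divided by size factors. The deposited fold change and its standard error are on the log2 scale. The deposited test statistic is a score: in all 6180 genes where it is not 0, the absolute log2 fold change minus the absolute statistic times the SE equals 1. The deposited p-value therefore tests against an absolute log2 fold change of at most 1, and not against no change. The deposited adjusted p-values match a Benjamini-Hochberg adjustment over 7068 genes, and the other 13669 genes have none; every gene with one has a mean of at least 11.3. Which treatment is the numerator is not given in the sources used here.

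Whole counts per library were recovered from the deposited means. A gene counted once in 1 library has a mean of 1 over 4 times that library's size factor, so the lowest means give the 4 size factors, and the sign of the fold change places each library in the numerator or the denominator. The size factors were 1.57 and 0.958 for the numerator and 1.06 and 0.65 for the denominator libraries. For each gene, all sets of 4 whole counts that give the deposited mean within a relative tolerance of 6e-15 were searched near the split that the fold change gives. The solution was unique for 20733 of 20737 genes (99.98%). The other 4 genes, with means of at least 2229 and 2.65% of the summed means, had several solutions and were left out of everything computed from counts. Size factors recomputed from the recovered counts as medians of ratios differed from the recovered ones by at most 0.00575%. The recovered libraries are known as larger or smaller within a treatment and cannot be matched to the replicate numbers of the labels. Genes with at least 1 count numbered 17900 and 15748 in the numerator and 15239 and 13699 in the denominator libraries.

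The recovery and the tests were tested on simulated data for the 2 treatments with 2 libraries each. With counting noise alone (18978 genes), 99.95% of genes were recovered exactly and 0 resolved genes were wrong. Of 7523 genes tested there, the exact test called 86 of 100 genes changed by a log2 fold of 2, all 100 changed by 3, and 0 unchanged genes. The estimated coefficients of variation were 1.38% and 2.67% there, although none was simulated, so estimates of that size cannot be separated from 0. With a coefficient of variation of 10% added (7484 genes tested), the exact test called 81 of 100 and 100 of 100, and the estimated coefficients were 9.99% and 10.2%. In both simulations the changed genes were drawn only from genes with at least 100 counts over the 4 libraries. The shares called therefore do not hold for the sparser genes tested.

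Before the data were examined, the main result was set as the deposited adjusted p under 0.05 if the table held only the submitters' comparison, with other thresholds, filters, sizes of change and null distributions as alternatives. The plan for counts per library, a count model fitted to them, was set for deposited counts and was not applied to the recovered ones. The exact binomial test of summed counts, the spread within and between pairs, the share of rare genes the pairing of libraries by depth and the counts left out library by library were chosen after the data were seen. Spread was measured as chi-square given the sum of a pair, over genes with at least 20 counts in it, with 1000 bootstrap draws over genes. Log2 normalized counts for correlations had 0.5 added to each count. The named genes were to be those with the largest rise and fall among genes that passed, with a mean of at least 100 and both libraries of a treatment on the same side of both others, plus members of fixed lists and a set of reference genes. The identifiers could not be paired with names by the tables used here, so at most 2 in each direction are printed. For the same reason the 20 gene lists fixed beforehand and the relation of fold change to coding length were not analysed here. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.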

Results

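Ribosome-protected RNA fragments were sequenced from HEK293T cells, an established human embryonic kidney cell line. Cycloheximide binds the ribosome and stops it during elongation, and C13-benzamidyl cycloheximide, called benzamide here, is a derivative of it. The study asked how the benzamide affects ribosome occupancy across the genome, with cycloheximide as the comparison. Cells received either compound at 350 µM for 1 min, and 2 libraries were made per treatment, 4 in all. The authors' deposited table holds 20737 genes, each with a mean normalized count over the 4 libraries, a log2 fold change and its p-value. It has no column per library. Whole counts per library were therefore recovered from the deposited means, with a unique solution for 20733 genes. The recovered totals were 706786 and 431918 counts in the libraries of the treatment in the numerator of the fold change, and 476875 and 290740 in those of the denominator. Which compound was the numerator is not given in the sources used here, so each sign below refers to the numerator over the denominator treatment and not to a named compound. Genes are given by their identifiers because no table used here pairs them with names, and at most 2 are named in each direction. For the same reason the class of RNA behind an identifier is not known here. A fold change of a gene therefore need not reflect ribosomes on a coding sequence.

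The largest well-counted differences reached about 20-fold in either direction. In the authors' deposited table, ENSG00000130520.10 had a log2 fold change of 4.44 (SE 0.19, adjusted p = 4.79e-68, mean normalized count 583), which is a 21.6-fold difference. Its normalized counts were 1001 and 1229 in the numerator libraries against 50.7 and 52.3 in the denominator libraries. ENSG00000137857.17 followed with a log2 fold change of 4.26 in the authors' deposited table (SE 0.27, adjusted p = 2.91e-29, mean normalized count 218), from recovered counts, before scaling, of 638 and 405 against 24 and 13. In the opposite direction, the authors' deposited table gave ENSG00000251741.1 a log2 fold change of -4.43 (SE 0.28, adjusted p = 1.73e-31, mean normalized count 185). It had 14.7 and 18.8 normalized counts in the numerator libraries against 315 and 392 in the denominator libraries. ENSG00000199377.1 had a smaller fall, with a log2 fold change of -2.69 in the authors' deposited table (SE 0.23, adjusted p = 2.58e-10, mean normalized count 138), from 40.1 and 33.4 against 252 and 226 normalized counts. Ratios of the summed counts had 95% Clopper-Pearson intervals of 4.10 to 4.73 and 3.78 to 4.77 on the log2 scale for ENSG00000130520.10 and ENSG00000137857.17. For ENSG00000251741.1 and ENSG00000199377.1 they were -4.90 to -3.95 and -3.02 to -2.36. These intervals cover counting error only. For ENSG00000130520.10 the numerator libraries, at 1001 and 1229 normalized counts, differed from each other by more than counting error, so its interval is too narrow.

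Few genes were shown to differ by more than 2-fold between the libraries of the 2 treatments. Of 7068 genes with an adjusted p in the authors' deposited table, 23 passed 0.05 (0.325%), 12 with a positive and 11 with a negative fold change, and 55 had an unadjusted p under 0.05. The deposited p-values test against an absolute log2 fold change of at most 1, so a passing gene is one whose difference exceeded 2-fold in these libraries. No label says that the libraries of a treatment came from separate cultures. A small deposited p-value therefore does not show that a difference would recur in other cultures. The absolute log2 fold changes in the authors' deposited table ran from 2.24 to 5.55 for the positive genes and from 2.28 to 5.65 for the negative genes. The medians of the signed values in the authors' deposited table were 3.97 and -2.81. Most of these genes had a mean normalized count under 100 in the authors' deposited table, and 5 positive and 3 negative genes reached 100. The same held for most genes tested: 877 genes reached 100, against 7068 with an adjusted p. All 23 had whole counts recovered, and in all 23 both numerator libraries lay on the same side of both denominator libraries. Selection for a large fold on these same libraries makes that nearly certain, so the 33.3% that chance gives for unselected genes is no yardstick here. In 6 of them, 4 positive and 2 negative, the treatment with the lower level had under 10 counts over its 2 libraries, so the size of those folds is loosely bounded. The 12 positive genes took 0.733% and 0.816% of the counts in the numerator libraries against 0.0562% and 0.0502% in the denominator libraries. The 11 negative genes took 0.0572% and 0.056% against 0.38% and 0.419%.

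**Figure D1:**
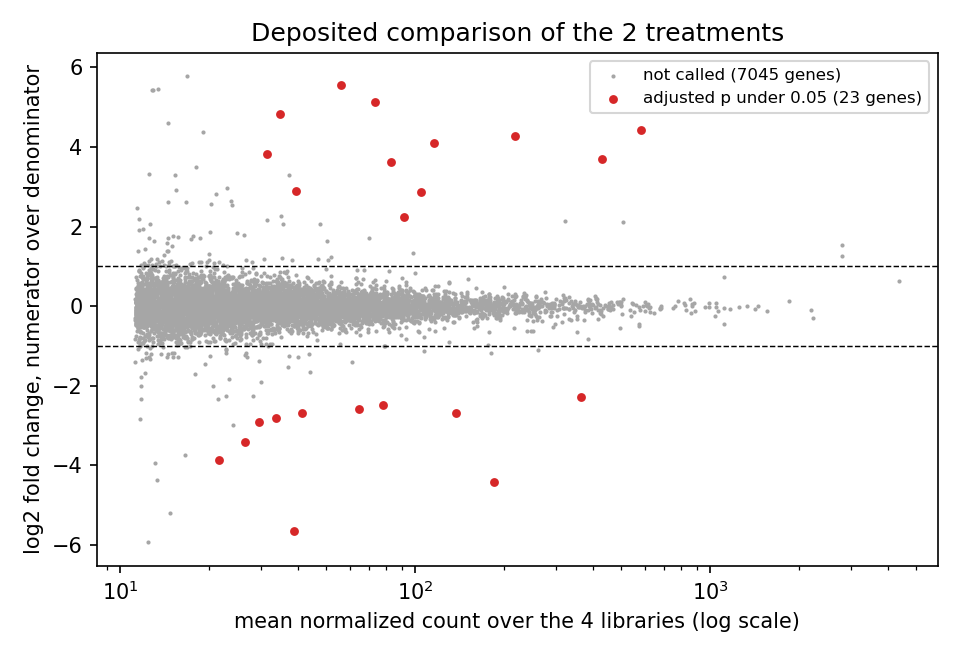
Log2 fold change in the authors' deposited table, numerator over denominator treatment, against the mean normalized count on a log axis. Points are the 7068 genes with an adjusted p, the 23 in red passed 0.05, and dashed lines mark log2 fold changes of -1 and 1.

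**Figure D2:**
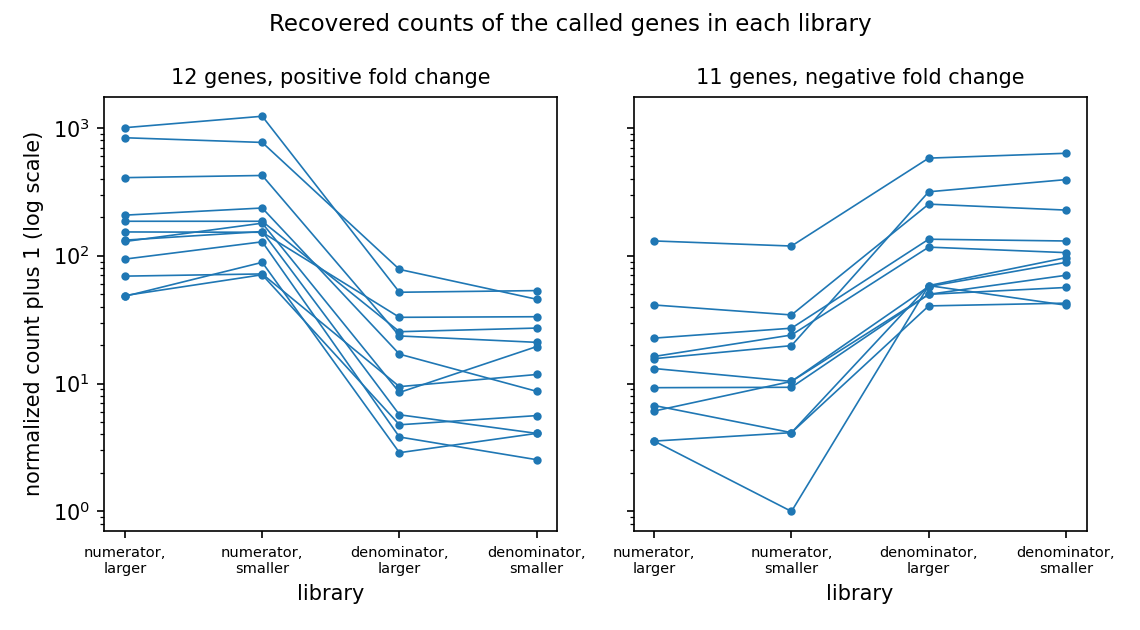
Normalized counts plus 1, on a log axis, of the 23 genes in each of the 4 recovered libraries, with 1 line per gene and no error bars. The 12 positive genes are higher in both numerator libraries and the 11 negative genes are higher in both denominator libraries; 1 gene had a library with no count and sits at 1.

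Relative to the bulk of genes, most abundant genes differed little between the treatments. Size factors set the typical gene near a log2 fold change of 0, so a change in total ribosome occupancy cannot be seen in these values. Over the 877 genes with a mean normalized count of at least 100, the median log2 fold change in the authors' deposited table was -0.0092. The middle 95% of these log2 fold changes in the authors' deposited table ran from -0.54 to 0.40, and the quartiles were -0.12 and 0.10. The 95% interval of the fold change, taken as a normal interval from the deposited SE, lay within a log2 range of -1 to 1 for 853 of these 877 genes (97.3%). It lay within -0.5 to 0.5 for 498 of them (56.8%). Of the 24 genes whose interval reached beyond -1 to 1, 8 passed the adjusted p of 0.05 and 16 did not. For 14 of those 16 the interval from the deposited SE spans the 2-fold limit, and for the other 2 it lies wholly beyond the limit without the gene passing after adjustment. The 10 genes with the highest means, together 4.78% of the summed means, had log2 fold changes from -0.29 to 1.55 in the authors' deposited table, and 0 of them passed the test (2 at an unadjusted p under 0.05). Over all 7068 genes with an adjusted p, the interval lay within -1 to 1 for 3201. The deposited SE sets the width of these intervals, and how much of it is counting error was not measured for the sparser genes.

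The libraries of a treatment were close to each other. Chi-square per degree of freedom over genes with at least 20 counts in the pair was 1.02 for the numerator libraries (8420 genes) and 1.01 for the denominator libraries (6993 genes), where counting alone gives 1. Between treatments it was 2.36 for the larger libraries and 2.01 for the smaller ones. The coefficient of variation beyond counting was 1.95% within the numerator pair (95% bootstrap interval over genes 0 to 3.31%) and 1.64% within the denominator pair (0 to 3.77%). Between treatments it was 14.6% for both pairs, with intervals of 12.8 to 16.5% and 12.2 to 17.1%. The 192 of 8550 and 94 of 6790 genes that themselves differed between the libraries compared were also left out. The coefficient between treatments was then 7.08% and 7.18% (intervals 6.65 to 7.48% and 6.55 to 7.75%). Those genes were chosen on the same counts, so leaving them out must lower it, and these values are biased low. Over the 873 genes with recovered counts and a mean of at least 100, Pearson's r of log2 normalized counts was 0.984 and 0.974 within treatments and 0.849 to 0.881 between them. With the called genes left out, r between treatments was 0.937 to 0.960. These correlations are across genes, which are not independent replicates. Agreement was not complete: 13 genes differed within the numerator pair and 6 within the denominator pair in exact binomial tests (two-sided, Benjamini-Hochberg adjusted p under 0.05). Of the called genes, 1 was among the 13, ENSG00000130520.10, and 0 were among the 6. Over genes with at least 100 counts in the pair, chi-square per degree of freedom was 1.13 and 1.07 (chi-square test across genes, p = 8.42e-07 and 0.0191). The coefficient of variation beyond counting was then 3.11% (interval 1.61 to 4.22%) for the numerator and 2.38% for the denominator pair, whose interval of 0 to 4.50% includes 0. Over genes with at least 20 counts, leaving out the 13 and 6 genes that differed gave chi-square per degree of freedom of 0.975 and 0.980. The coefficient was then 0% in both pairs, with upper bounds of 0.891% and 1.53%. Leaving out genes chosen on the same counts must lower these values. Because the libraries of a treatment differed by little more than the sampling noise over most genes, and no label says that they came from separate cultures, they were summed and counted as 1 sample per treatment. The difference between the treatments then has no replicate check. The deposited SE was wider than counting error: counting made up a median of 36.5% of its square over the 873 genes with a mean of at least 100 (quartiles 34.7 and 37.6%).

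**Figure D3:**
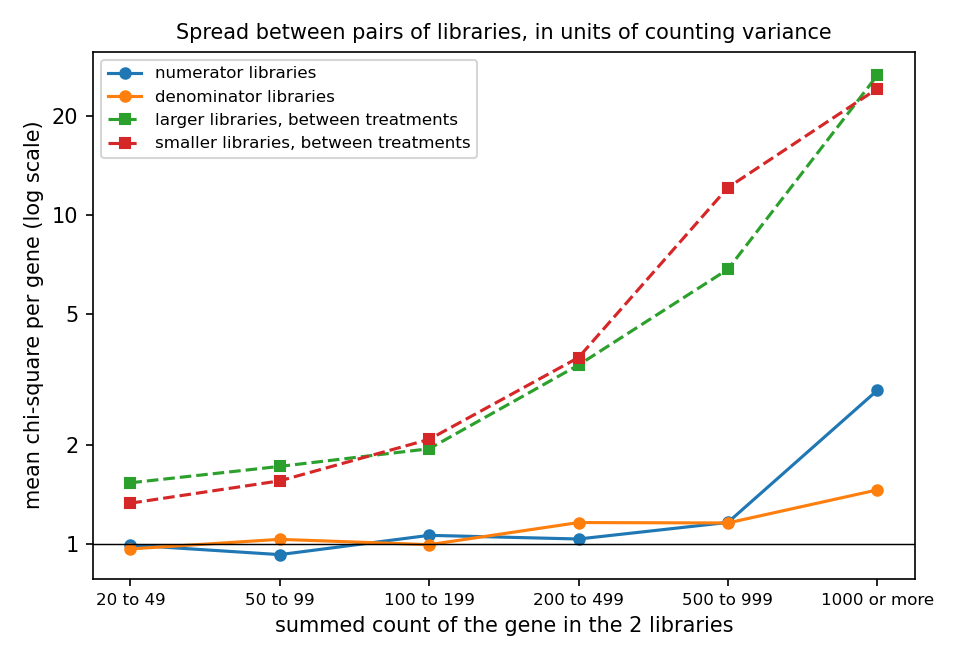
Mean chi-square per gene, on a log axis, for pairs of libraries within a treatment (circles) and between treatments (squares), by the summed count of the gene in the pair. Counting alone gives 1; pairs within a treatment lie between 0.931 and 1.17 below 1000 counts and at 2.94 and 1.46 above, and pairs between treatments rise to 26.6 and 24.3.

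An exact binomial test of the summed counts against the same 2-fold limit called 53 of 7064 genes (two-sided, Benjamini-Hochberg adjusted p under 0.05), 33 higher in the numerator and 20 higher in the denominator libraries. They included all 23 genes that passed in the authors' deposited table. This test compares the libraries and not the treatments. The same test between the libraries of a treatment called 0 genes for the numerator and 1 for the denominator, with 3 and 2 at an unadjusted p under 0.05. Between single libraries of different treatments it called 39 genes for the larger and 26 for the smaller libraries, with 65 and 55 at an unadjusted p under 0.05. Without the larger denominator library, the summed test called 30 genes in place of 53. Of the 30, 14 were higher in the numerator and 16 higher in the denominator libraries. That left 290740 of the 767615 denominator counts, and so less power. Without the smaller denominator library the summed test called 46, 25 and 21.

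Genes with few counts were seen more often in the numerator libraries. Among the 4016 genes with 1 count over all 4 libraries, that count fell in a numerator library for 73.4% (95% Wilson interval 72.0 to 74.8%), against 59.6% from the size factors. The share was 69.0% for genes with 2 to 4 counts (interval 67.9 to 70.0%) and 64.0% for genes with 5 to 9 (63.1 to 64.8%). It was 59.5% for genes with at least 100 and under 200 counts (59.4 to 59.7%). The libraries of a treatment also differed here: of the genes with 1 count that fell in the numerator libraries, 67.6% were in the larger one (65.9 to 69.3%), against 62.1% from the size factors. In the denominator libraries it was 68.7% (65.9 to 71.4%), again against 62.1%. The intervals of the shares therefore understate the difference between libraries. Genes with under 20 counts in all made up 2.89% of the numerator and 2.39% of the denominator counts.

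**Figure D4:**
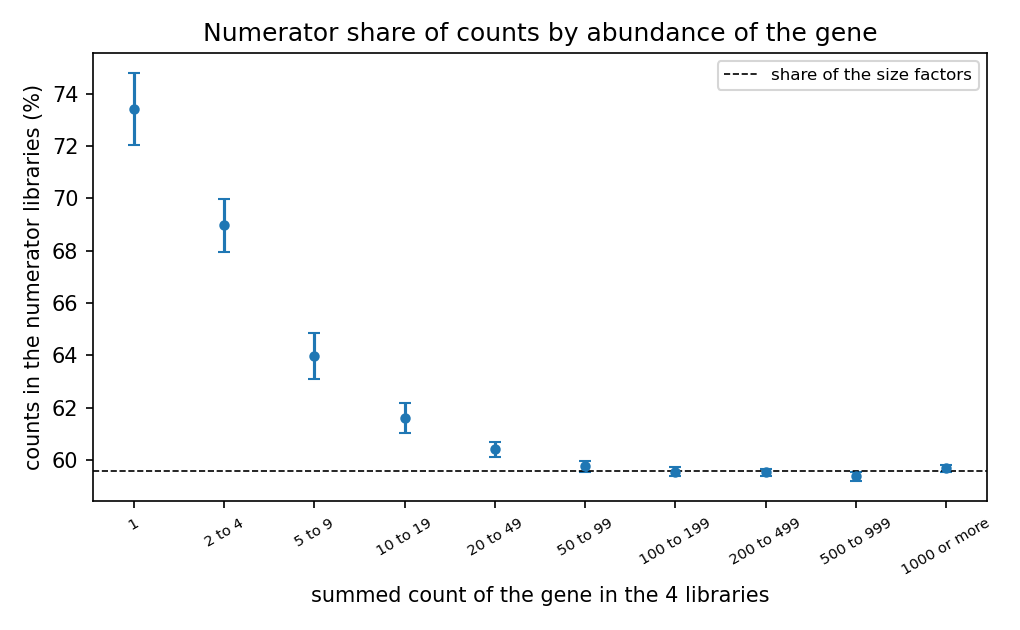
Share of counts in the numerator libraries, in percent, by the summed count of the gene over the 4 libraries, with 95% Wilson intervals. The dashed line is the share from the size factors, 59.6%; the share falls from 73.4% for genes with 1 count to 59.5% for genes with at least 100 and under 200, and the axis does not start at 0.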

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

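The exact tests of summed counts, the parts of the empirical spread taken singly, and all alternatives for them, for the spread, for rare genes and for the named genes, were chosen after the data were seen. The 23 genes of the authors' deposited table became 17 at an adjusted p under 0.01 and 24 under 0.1, and stayed at 23 with an absolute log2 fold change of at least 1 required. Adjusting over every gene gave 19, over means of at least 10 gave 22, and over means of at least 100 gave 8, since sparser genes were then not tested. A null of no change gave 88 genes, 43 positive and 45 negative, and 139 with the empirical spread of the statistic (SD 0.776); both hold all 23. The 88 follow from dropping the 2-fold limit, and the step from 88 to 139 from the narrower spread: its SD alone gave 140 and its median alone 88. The exact test called 53 genes, and 245 with a null of no change, again without the limit; library totals as scaling, which moved every log2 fold change by only 0.00847, gave the same 53. Leaving out 1 library at a time gave 30 to 50 genes, 29 to 49 of them among the 53. The 30 came without the larger denominator library, 14 positive and 16 negative in place of 33 and 20. That left 290740 of the 767615 denominator counts, and so less power. Whether this accounts for the drop was not tested. All 24 alternatives for the named genes kept their direction and stayed inside the counting interval, with shifts of at most 0.23 on the log2 scale. Of 12 alternatives for the spread, 10 stayed inside its bootstrap interval. The others, without the genes that differ, lowered the coefficient of variation between treatments to 7.08% and 7.18%, as leaving out such genes must. No paired analysis was possible because the table carries no replicate numbers and the recovered libraries cannot be matched to them. Pairing them by depth instead, larger with larger as strata of the exact test, gave the same 53 genes. Differences between the libraries of a pair correlated at 0.136 across 873 genes between treatments, and at 0.046 without 2 genes that differed in both. The planned gene list and coding length alternatives were not run. The count models were planned for deposited counts and were not fitted to the recovered ones. Depth limits the sparser genes: those with a mean under 11.3 have no adjusted p.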

Other observations

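Of the tests in this part, only the thinning of the numerator libraries to the depth of the denominator libraries was set before its result was seen; the others were chosen afterwards. The 3 genes that differed between libraries within both treatments did so in the same direction, higher in the larger library of each. They were picked out after their values were seen. Their counts were 1564 and 619 against 345 and 37, 1020 and 384 against 179 and 46, and 25 and 0 against 25 and 0, numerator libraries first. The log2 fold changes of the first pair in the authors' deposited table were 2.10 and 2.13, with an adjusted p of 1 for both.

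The libraries of a treatment differed by little more than counting over genes with at least 20 counts, though not over the rarest genes. Separate cultures with a coefficient of variation of 10% or more per gene are argued against by the upper bounds, of which the higher was 3.768%. A finished library read again with the same processing is argued against by the genes that differed within pairs, 13 and 6. A second reading with other processing was not tested. The larger library of a treatment held 1.64 times the counts of the smaller one in both treatments, and the ratio of these ratios was 0.9977 (95% counting interval 0.992 to 1.004). This is consistent with 1 pool of ligations carried through the later steps 2 times, a hypothesis found and tested on the same values. Closely matched cultures pooled in equal proportions stay open. No biological explanation was tested for this pattern.

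The 23 called genes may reflect the compounds, the difference that the design names, which stays open and untested. Counting noise is argued against: the exact test against a 2-fold difference called at most 1 gene between libraries of the same treatment and at least 26 between libraries of different treatments. Scaling is argued against as the whole cause, since calls went both ways. Any shift common to all genes would leave at least 14 of the 23 beyond a log2 fold change of 1. That number follows largely from calls in both directions that were selected for large folds, so it is no separate evidence. The linker barcode cannot be told apart from the treatment, because every library of a treatment carried the same one. Most genes moved little, with a median absolute log2 fold change of 0.108 at means of at least 100, but a bias at a few footprint ends would leave that median low too.

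Depth did not remove the excess of rarely seen genes: thinned to the 767615 counts of the denominator libraries, the numerator libraries still showed 17945 genes on average over 20 draws (SD 24.0) against 16220, an excess of 1725.1. It was not confined to 1 library: at 290740 counts each, the numerator libraries showed 14989 and 14601 genes and the denominator libraries 13991 and 13699, a smallest difference of 610.2. Within treatments the larger library showed 388 and 292 more genes than the smaller one, while the 610.2 is between the smaller numerator and the deeper, larger denominator library. Reads piled on few rare genes are argued against for the genes with 1 count in all, since each of these adds only 1 count. Their rate was 1.874 times higher in the numerator libraries (95% interval 1.75 to 2.01, counting error only). With 1 library left out the rate was 1.55 to 2.09 times, but over a different set of genes than these. The rate of 1.874 restates the share of 73.4% that showed the pattern, so it is no separate test. A broader background of fragments in the numerator libraries, the linker and the compound all remain open, and none of them was tested.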
